A study of Mus musculus with 6 samples.

How the data were processed

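RNA from 6 samples of 4T1 clones was sequenced by the authors with a standard Illumina mRNA protocol, 3 libraries from clones labelled breast cancer stem cell and 3 from clones labelled breast cancer cell. Groups were taken from the tissue labels and replicate numbers from the sample titles. Per the labels, clones were collected after 14 days from wells seeded with 1 cell in 300 or 200 µL of medium, depending on the protocol text. The labels do not say whether 10 clones went into each library or which libraries came from the same experiment.

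The deposited values are RPKM made by the authors, with 1 file per library listing 19179 genes with Ensembl identifiers, coordinates and a gene length. Whether the authors counted reads or read pairs is not stated, and they are called reads here. The submitters' notes name Bowtie2 2.0.6, TopHat2 2.0.9 and the build mm9 without saying what each was used for, and the counting program and the strand of counting are not stated. Of the genes, 99.6% had an identifier in GENCODE M21. Of these, 80.6% had the same start and end on GRCm38 and 99.5% lay within 50 kb, so coordinates are given on GRCm38. Spreadsheet conversion had turned 25 symbols into numbers, and these were restored by identifier. The files list no gene at 0 in all 6 libraries, the smallest total being 2 reads.

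Multiplying each value by its gene length gave whole multiples of a fixed step in every library (tolerance 0.01), which returned the reads behind each value. Reads in genes were 21558159, 22838870 and 21196572 in replicates 1 to 3 of the stem-labelled clones and 16830762, 15357608 and 15402338 in those of the other clones. They were 0.757, 0.753 and 0.658 and 1.41, 1.23 and 1.53 of the library totals implied by the deposited unit. Intervals for single counts were not computed, since the comparison rests on the spread between libraries. At these depths 1 read in a gene of 1 kilobase is worth 0.0311 to 0.0993 RPKM.

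The comparison used limma 3.58.1 in R 4.3.3 on log2(RPKM + 1) of the deposited values with no further scaling, with a trend in the variance. Genes with RPKM of at least 1 in at least 3 of the 6 libraries were tested, which left 10097 and removed 9082. Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. Of 42 gene lists, 36 had at least 5 tested members and were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists, and again with the correlation estimated. Counts of list members were taken over all genes tested and also adjusted over the list alone. The comparison, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except where said otherwise. The rule named the 10 largest increases and the 10 largest decreases among called genes with complete separation of the groups and a mean of at least 5 RPKM, leaving out symbols without a known function, then up to 4 members of each list with the smallest p, and 14 genes chosen in advance. Not all of the genes the rule allows are described. The pluripotency reads were singled out after their values were seen.

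The settings varied were the replicate number as a block, leaving out each library, upper-quartile scaling, no filter, a filter of mean RPKM at least 5, a pseudocount of 0.1, limma without the trend or with robust variance estimates, a change of at least 2-fold, and an estimated correlation for the lists. The alternatives chosen after seeing the data were a correction for gene length and GC content, the block together with that correction, rescaling to the reads summed over genes, and limma-voom on the recovered reads with median-of-ratios scaling. The correction regressed each library's deviations from the gene means on natural splines with 5 degrees of freedom of log2 length and of GC content, which was known for 99.9% of tested genes, and subtracted the fit. Shared sequence was measured as the share of 50-base stretches of a gene's longest transcript that also occur in a transcript of another gene in GENCODE M21.

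The test was checked on simulated data with 200 changed genes. With no library trend it found 67% of 2-fold and 99% of 4-fold changes and called 10 unchanged genes. With the length and GC trends of these libraries added and not corrected, it called 3238 unchanged genes (32.7%), and with the correction 71 (0.717%). The added trends were the spline fits that the correction subtracts, so this does not test whether the correction separates bias from differences between the groups. The list test called 0 of 40 unmoved lists and found the list moved by 1.5-fold (camera adjusted p = 2.85e-25). Its genes were simulated independently of each other, so it does not test the preset correlation. In the data the estimated correlation was 0.470 for the oxidative phosphorylation list and 0.626 for the ribosomal protein list. In splits of the real libraries that mixed the groups, the list test called up to 13 lists. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.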

Results

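The comparison was between clones grown from isolated 4T1 cells, a mouse mammary carcinoma line from the BALB/c strain that spreads spontaneously to distant organs. Cells were seeded at 1 per well in 96-well plates and cultured for 14 days, after which 10 clones of each of 2 kinds were collected in each of 3 batches from 3 independent experiments, or in all batches together (the labels allow both readings). Messenger RNA sequencing gave 6 libraries, 3 from clones whose tissue label is breast cancer stem cell (here stem-labelled) and 3 from clones labelled breast cancer cell (here other). The labels abbreviate the kinds as SC and NSC and give neither the meaning of the letters nor how a clone was assigned to a kind. Reads assigned to genes numbered 21196572 to 22838870 per library in the stem-labelled clones and 15357608 to 16830762 in the other clones. The title of the series speaks of cell states that set the ability to metastasize, and the comparison asks which transcripts differ between the kinds of clone. Levels below are means ± SD in RPKM with n = 3 libraries per group, and positions are on the GRCm38 build. RPKM are reads scaled by gene length in kilobases and by the authors' library total. Changes are log2 fold changes of RPKM + 1 (stem-labelled minus other) ± SE, and the added 1 makes them smaller for genes of low level.

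The stem-labelled libraries held far more transcript of Gpnmb, a transmembrane glycoprotein of lysosomes and melanosomes. They also held far more of the endocytic receptor Lrp1 and of the type IV collagen chain Col4a1. Lower there were 39 of 55 nuclear-encoded oxidative phosphorylation genes, 40 of 54 ribosomal protein genes and the keratin Krt14. Library preparation or counting cannot be told apart from the groups. Reads in genes were 0.658 to 0.757 of the authors' library total in the stem-labelled libraries and 1.23 to 1.53 in the others. The tests of whole gene lists below passed with a preset correlation between genes and not with an estimated correlation. Gpnmb rose from 1.25 ± 1.25 to 78.3 ± 50.3 RPKM, a change of 5.10 ± 0.46. Rpl39, a ribosomal protein gene, stood at 419 ± 89.8 RPKM against 18496 ± 11124 RPKM, a change of -5.21 ± 0.58. Cdh1, which encodes E-cadherin, rose by 2.04 ± 0.22 and so did Twist1, a repressor of E-cadherin, by 1.57 ± 0.20.

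Of 10097 genes tested, 5577 (55.2%) changed at an adjusted p under 0.05 (limma), 3014 of them higher and 2563 lower in the stem-labelled clones. All 3 libraries of a group lay above all 3 of the other group for 6415 genes (63.5%), where chance gives 10%. The split by direction depended on the scaling: with the values rescaled to the reads summed over genes in each library, 5926 genes were higher and 1245 lower, since the median change of all genes moved from 0.11 to 0.86. All changes below are on the deposited scale and are best read against that median. Fold changes also followed gene length, from a median of -1.17 in the shortest decile of tested genes to 0.72 in the longest. The share of genes called higher ran from 5.24% in the shortest decile to 59.6% in the longest, and the share called lower from 61.1% to 4.76%. Counts of list members below are best read against these shares. A value after a correction for length and GC content is therefore given beside many of the named genes. In simulated data with such trends and no correction the test called 32.7% of unchanged genes, and with the correction 0.717%. The simulated trends were fitted with the same splines that the correction subtracts, so the drop was largely fixed by design. It does not show whether the correction also removes differences between the kinds of clone that follow length or GC content. After that correction 3420 of the 5577 genes were called in the same direction and 38 in the opposite direction.

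**Figure D1:**
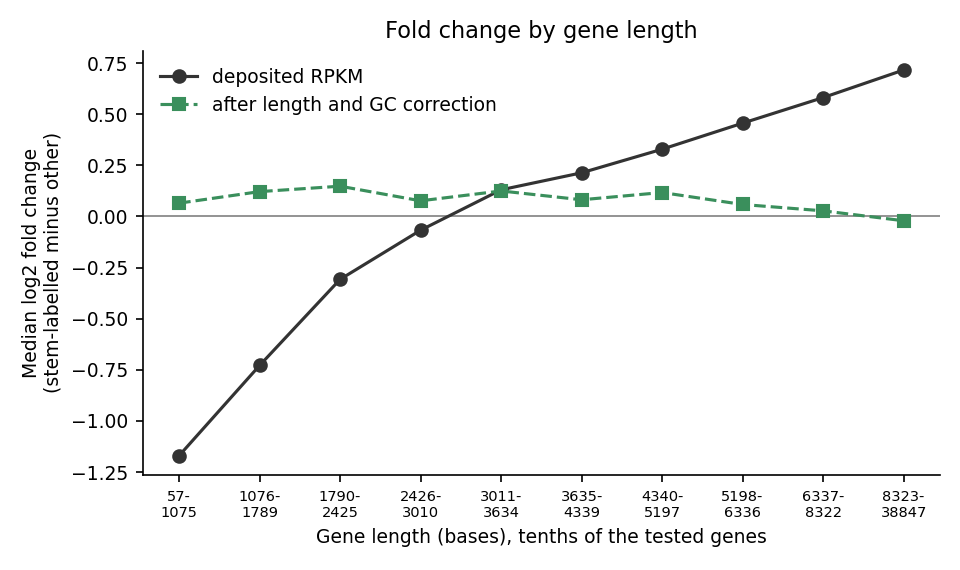
Median log2 fold change (stem-labelled minus other) of the tested genes in deciles of gene length, in bases, for the deposited RPKM and after the correction for length and GC content. The deposited values run from -1.17 in the shortest decile to 0.72 in the longest, and the corrected medians lie between -0.02 and 0.15.

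The 10 genes with the largest increase were Gpnmb, Scara5, Olfm1, Tnrc18, Nptx1, Rn18s-rs5, Lrp1, Amigo2, Xdh and Apcdd1, with changes from 3.18 to 5.10. Gpnmb (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929) changed by 4.29 after the correction, and its level in replicate 2 of the stem-labelled clones, 136 RPKM, was above the 47.4 and 51.2 RPKM of replicates 1 and 3. Scara5 (ENSMUSG00000022032, chromosome 14, 65666403 to 65764826), a scavenger receptor that binds ferritin, rose from 0.568 ± 0.332 to 22.5 ± 5.73 RPKM (3.90 ± 0.24, 3.18 after the correction). Nptx1, a pentraxin known from neurons, rose from 20.2 ± 8.72 to 234 ± 51.2 RPKM, and Olfm1, a secreted olfactomedin, from 3.16 ± 1.03 to 52.2 ± 9.30 RPKM. Lrp1 rose by 3.34 ± 0.31 and Apcdd1, an inhibitor of WNT signalling, by 3.18 ± 0.23. Rn18s-rs5 is annotated as a sequence related to 18S ribosomal RNA, stood at 226 ± 44.2 against 20.5 ± 2.77 RPKM, and shares 66.4% of its 50-base stretches with other genes. For these genes the adjusted p ran from 9.21e-05 to 0.000336, and all 10 were also called after the correction.

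The 10 genes with the largest decrease were Rpl39, Snora33, Galk1, Rpl22l1, mt-Atp6, Pgls, Rps14, mt-Nd3, Prr7 and Tmem205, with changes from -5.21 to -4.60. Galk1 (ENSMUSG00000020766, chromosome 11, 116008457 to 116012719), the galactokinase of galactose breakdown, fell from 3802 ± 1697 to 112 ± 53.3 RPKM (-5.11 ± 0.45, -3.66 after the correction). Rpl39 (ENSMUSG00000079641, chromosome X, 37082520 to 37085402) changed by -4.71 after the correction and shares 16.5% of its 50-base stretches with other genes. Pgls, an enzyme of the pentose phosphate pathway, fell from 865 ± 236 to 31.4 ± 11.2 RPKM. Snora33 rested on 5 reads in the stem-labelled libraries against 261 in the others and lies wholly within an exon of the ribosomal protein gene Rps12. Among these 10 genes mt-Atp6 and mt-Nd3 moved most with the correction, to -2.38 and -1.58.

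**Figure D2:**
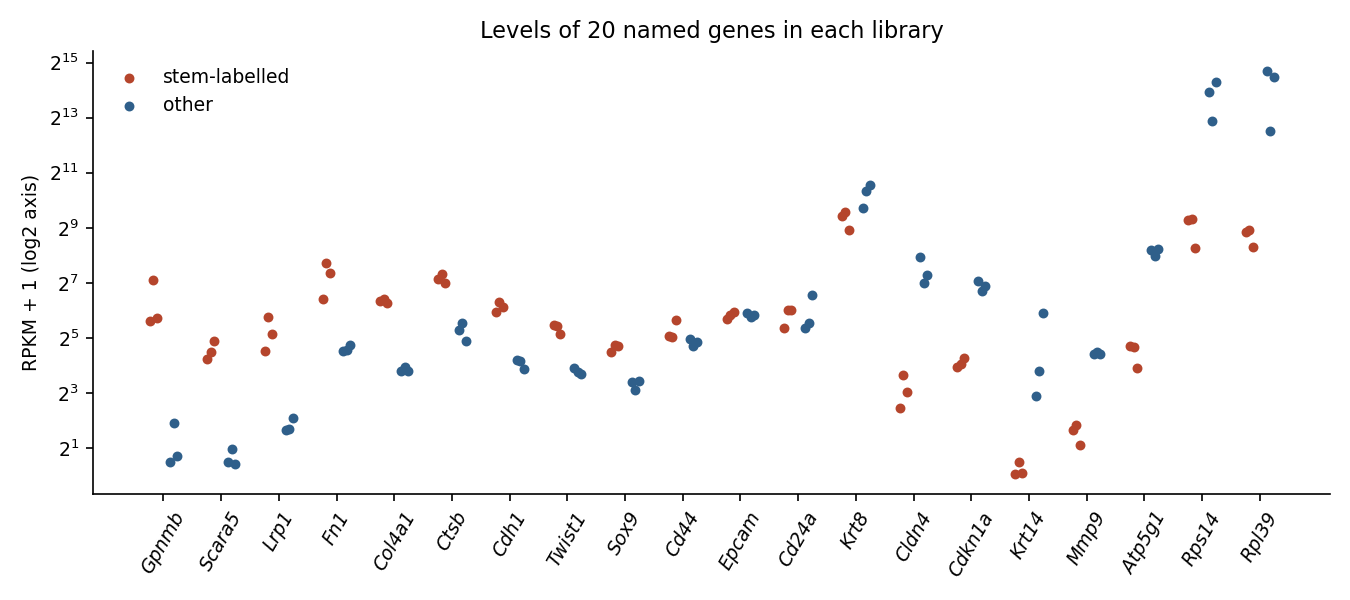
Levels of 20 named genes as RPKM + 1 on a log2 axis, 1 point per library, stem-labelled clones in red and other clones in blue. Gpnmb to Sox9 lie higher in the stem-labelled clones, Cd44 to Krt8 did not pass the test, and Cldn4 to Rpl39 lie lower.

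Of 36 autophagy and lysosome genes, 17 rose in the stem-labelled clones, 2 fell and 17 did not pass. The counts were the same when adjusted over the list alone. The median change was 0.68, or 1.5 on rescaling to summed reads, which moved the median of all genes from 0.11 to 0.86. The lysosome and matrix genes together had a median length of 4739 bases. Of all tested genes of 4340 to 5197 bases, 37.2% were called higher. The protease Ctsb rose by 1.91 ± 0.25 and the carboxypeptidase Ctsa by 1.69 ± 0.23, to 142 ± 16.3 and 35.0 ± 7.80 RPKM (1.31 and 1.41 after the correction). Both share exon sequence with a gene on the opposite strand, and the strand used in counting was not stated. Npc1, a lysosomal cholesterol exporter, rose by 1.17 ± 0.17 but only by 0.34 after the correction, where it missed the threshold. The list passed its test (camera adjusted p = 0.0120, corrected median 0.93), with adjusted p = 0.785 when the correlation between genes was estimated. Without replicate 2 of the stem-labelled clones its adjusted p was 0.0513, with a median of 0.54.

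Of 23 extracellular matrix genes tested, 15 rose, 3 fell and 5 did not pass, with the same counts adjusted over the list alone. The median was 1.20, or 2.01 on rescaling, where the median of all genes was 0.86. Col4a1 (ENSMUSG00000031502, chromosome 8, 11198423 to 11312826) rose from 13.3 ± 0.781 to 79.8 ± 3.79 RPKM (2.5 ± 0.20, 2.35 after the correction). Col4a2, its partner chain in type IV collagen, rose by 2.13 ± 0.22 and the laminin chain gene Lamc1 by 2.27 ± 0.19 (1.48 after the correction). Fn1, which encodes fibronectin, rose from 23.4 ± 1.85 to 152 ± 62.5 RPKM (2.55 ± 0.33, 1.70 after the correction). Lama3, a laminin chain of epithelial basement membranes, fell from 2.75 ± 1.08 to 0.107 ± 0.0117 RPKM (-1.72 ± 0.22, -2.71 after the correction). The camera adjusted p was 0.0120, and adjusted p = 0.740 with an estimated correlation. With no filter on low values the median was 0.06 and the adjusted p 0.0858, and with the replicate block and the correction together the adjusted p was 0.0734.

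Of 55 nuclear-encoded oxidative phosphorylation genes, 39 fell, 0 rose and 16 did not pass (40 fell when adjusted over the list alone), with a median of -1.55 that became -0.92 after the correction and -0.62 on rescaling to summed reads. Atp5g1, a subunit of the ATP synthase, fell from 280.0 ± 24.7 to 21.2 ± 6.4 RPKM (-3.71 ± 0.28), and Uqcrc1 of complex III fell by 3.23 on the log2 scale, to 58.9 ± 15.1 RPKM. Ndufb8 of complex I changed by -2.43 ± 0.24 and Cyc1, the cytochrome c1 gene, by -2.91 ± 0.28 (-2.65 and -1.34 after the correction). Of the 15 transcripts encoded in the mitochondrial genome, 13 fell and 2 did not pass, the same adjusted over the list alone, with a median of -3.90 (-1.58 after the correction). The ribosomal RNA mt-Rnr2 stood at 36.6 ± 9.88 against 974 ± 495 RPKM and mt-Co3 at 32.8 ± 2.24 against 745 ± 445 RPKM (-2.46 and -2.28 after the correction). Almost every 50-base stretch of mt-Co3, mt-Atp6 and mt-Nd3 also occurs in another annotated gene. The camera adjusted p was 2.96e-10 for the nuclear and 1.49e-06 for the mitochondrial list, and adjusted p = 0.740 for both with an estimated correlation.

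Of 54 ribosomal protein genes tested, 40 fell, 0 rose and 14 did not pass (41 fell when adjusted over the list alone), with a median of -1.71, or -1.09 after the correction and -0.77 on rescaling. Rps14 fell from 14394 ± 6315 to 522 ± 188 RPKM (-4.75 ± 0.50) and Rpl34 from 2257 ± 1538 to 185 ± 45.7 RPKM (-3.42 ± 0.47). Rps28 changed by -2.52 ± 0.33 and Rplp2 by -2.23 ± 0.30. The camera adjusted p was 1.00e-09, and adjusted p = 0.740 with an estimated correlation. Of 17 replication-dependent histone genes, 14 fell, 0 rose and 3 did not pass, the same adjusted over the list alone, with a median of -1.62 (-0.88 after the correction). Hist1h4h stood at 1.08 ± 0.575 against 21.1 ± 7.22 RPKM and Hist1h2bj at 0.321 ± 0.321 against 8.0 ± 1.23 RPKM (-1.67 and -0.88 after the correction). Both histone genes are in the shortest decile of tested genes (57 to 1075 bases), of which 61.1% were called lower. These genes rest on few reads, 46 in the stem-labelled and 339 in the other libraries for Hist1h4h, and share much of their sequence with other histone genes. The histone list had a camera adjusted p of 1.49e-06, and adjusted p = 0.740 with an estimated correlation.

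**Figure D3:**
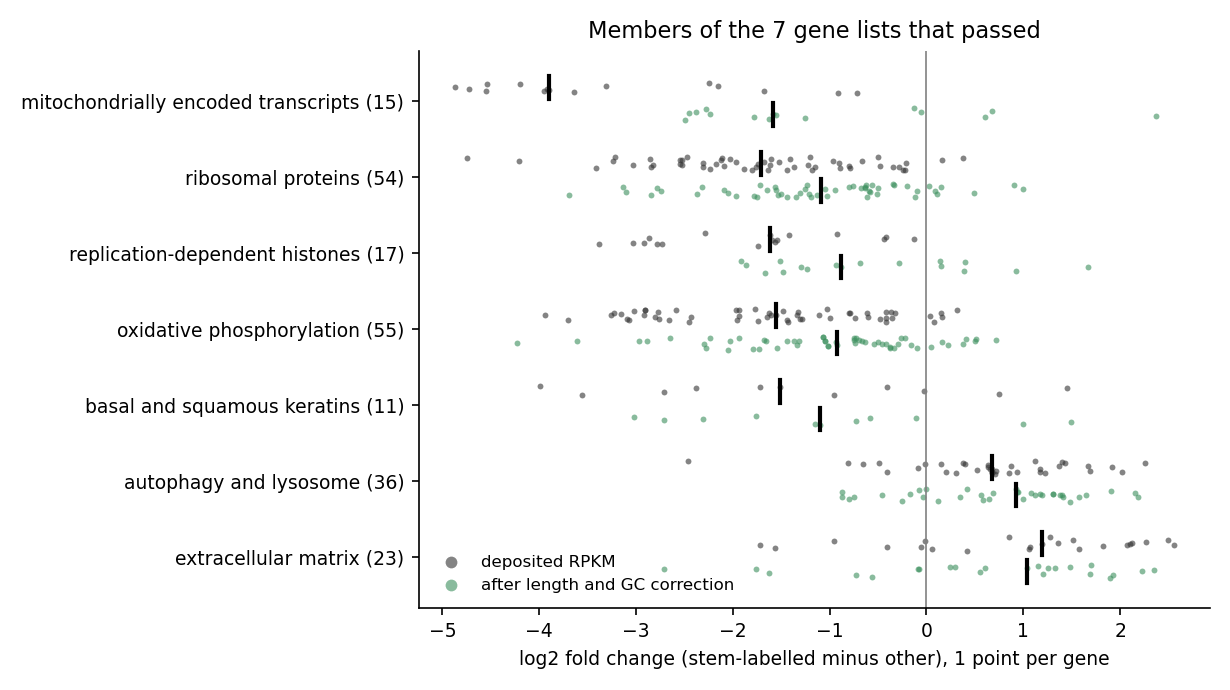
Log2 fold change (stem-labelled minus other) of each tested member of the 7 gene lists that passed, 1 point per gene, with the number of genes in brackets and a bar at the median, for the deposited RPKM in grey and after the length and GC correction in green. The mitochondrially encoded transcripts have the lowest median, -3.90, and -1.58 after the correction.

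The composition of the libraries moved with these groups. Mitochondrially encoded transcripts took 1.07 ± 0.138% of the reads in genes in the stem-labelled libraries and 5.71 ± 2.88% in the others, and ribosomal protein genes 8.91 ± 1.62% and 21.7 ± 3.94%. The 20 most abundant genes of a library took 10.4 ± 1.44% and 23.5 ± 3.48%. Lgals1, which encodes galectin-1, took 1.09 ± 0.362% and 4.70 ± 1.04%. Reads in genes were 0.723 ± 0.0558 of the authors' library total in the stem-labelled libraries and 1.39 ± 0.149 in the others. None of these measures overlapped between the groups, and with 3 libraries against 3 an exact permutation test cannot give a two-sided p below 0.1.

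**Figure D4:**
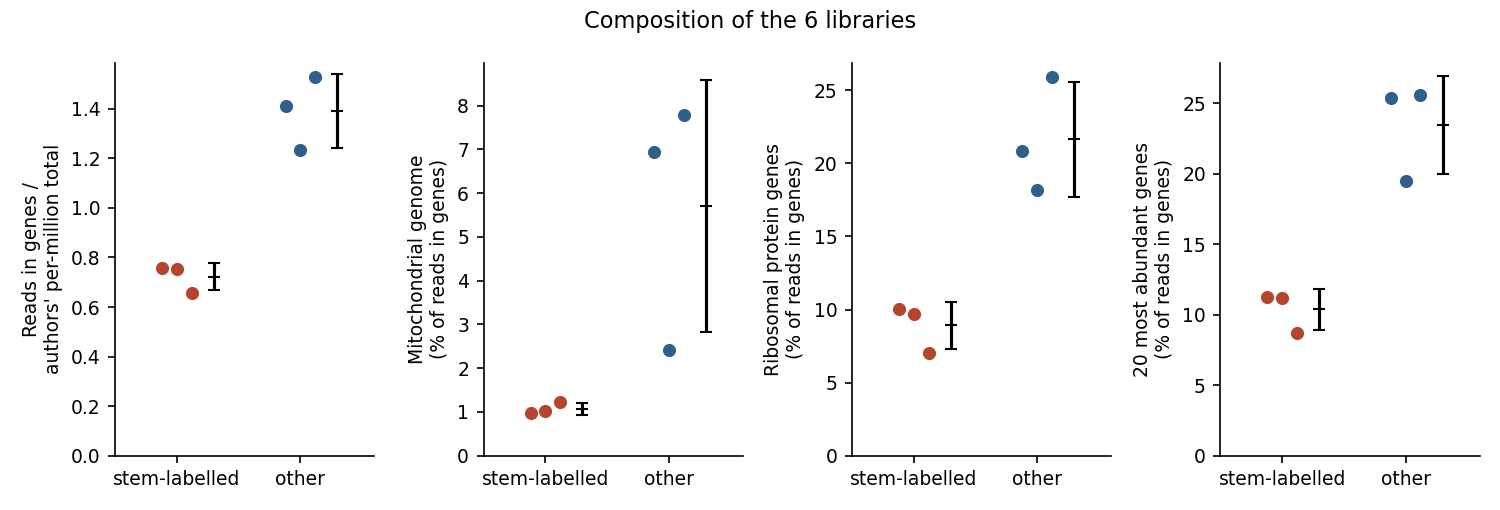
Composition of each library, with 1 point per library and the mean ± SD (n = 3) beside it: reads in genes over the authors' library total, and the percent of reads in genes from the mitochondrial genome, from ribosomal protein genes and from the 20 most abundant genes. The stem-labelled and other libraries did not overlap on any of the 4 measures.

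Of 11 genes of the basal and squamous keratin list tested, 7 fell in the stem-labelled clones, 2 rose and 2 did not pass, the same adjusted over the list alone, with a median of -1.51 (-1.10 after the correction). Krt14, a keratin of basal epithelium, stood at 0.162 ± 0.201 RPKM against 6.44, 12.8 and 59.4 RPKM in the other libraries (-4.00 ± 0.62). Sfn, the epithelial 14-3-3 sigma gene, fell from 98.1 ± 53 to 6.95 ± 2.56 RPKM, and Lgals7, which encodes galectin-7, from 6.67 ± 0.804 to 0.168 ± 0.110 RPKM. After the correction these 3 genes changed by -3.02, -2.31 and -1.10, and Lgals7 rests on 14 reads in the stem-labelled and 211 in the other libraries. The camera adjusted p was 0.0263, and adjusted p = 0.740 with an estimated correlation. The call was lost without replicate 1 of the stem-labelled clones (median -1.44, adjusted p = 0.0523). It was also lost without each library of the other clones, with medians of -0.26, -0.37 and -0.22 without replicates 1, 2 and 3. There the filter, applied again to the libraries left, removed Krt14, Lgals7 and Lama3, which lay below 1 RPKM in each stem-labelled library. These losses therefore do not separate dependence on a library from the change of members. With no filter on low values and with a filter of mean RPKM at least 5 the call was lost too, with medians of -0.41 and -0.68.

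Neither the epithelial nor the mesenchymal list passed, and each held genes that rose and genes that fell. Of 32 epithelial junction and identity genes, 7 rose, 10 fell and 15 did not pass (camera adjusted p = 0.243). Of 14 mesenchymal genes 8 rose, 3 fell and 3 did not pass (camera adjusted p = 0.286). The medians were -0.35 and 1.02, or -0.29 and 0.81 after the correction, so the tests do not exclude a shift of either list. Cdh1 (ENSMUSG00000000303, chromosome 8, 106603351 to 106670246) rose from 16 ± 1.98 to 68.9 ± 9.0 RPKM (1.45 after the correction). Cldn4 (ENSMUSG00000047501, chromosome 5, 134945119 to 134946934), a tight junction claudin, fell from 175 ± 62.7 to 7.72 ± 3.56 RPKM (-4.36 ± 0.35, -3.46 after the correction). The polarity gene Crb3 changed by -2.53 ± 0.40 (-1.39 after the correction). Twist1 (ENSMUSG00000035799, chromosome 12, 33957671 to 33959817) rose from 12.8 ± 1.16 to 39.9 ± 4.79 RPKM (2.79 after the correction). Vim, the mesenchymal intermediate filament, stood at 592 ± 82.8 against 441 ± 62.2 RPKM (0.43 ± 0.29, adjusted p = 0.233). Zeb1 had 13 reads in the stem-labelled and 1 in the other libraries and was not tested. Snai1, Krt8 and Epcam did not pass, with changes of -0.68, -0.90 and -0.03, and each of the 3 changed sign when the values were rescaled or corrected. Snai1 and Krt8 were called lower with upper-quartile scaling (-0.81 and -1.03, adjusted p = 0.0298 and 0.0351), with a filter of mean RPKM at least 5 (adjusted p = 0.0413 and 0.0491), with limma-voom (adjusted p = 0.0310 and 0.0204) and without replicate 1 of the other clones (-0.82 and -1.14, adjusted p = 0.0435 and 0.0367). Snai1 was also called without replicate 2 of the stem-labelled clones (-0.91, adjusted p = 0.0277) and Krt8 by limma without the trend (adjusted p = 0.0218). On rescaling to summed reads Epcam and Vim were called higher (0.90 and 1.37, adjusted p = 0.00575 and 0.00139). The median change of all genes was then 0.86, near that of Epcam.

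Markers used for mammary stem cells also went both ways. Of 14 tested, 3 rose, 3 fell and 8 did not pass, with the same counts adjusted over the list alone (adjusted p = 0.807). Sox9, a transcription factor of mammary progenitors, rose from 8.94 ± 1.20 to 24.1 ± 2.25 RPKM (1.34 ± 0.20, 0.82 after the correction). Itga6, the integrin alpha 6 gene, rose by 1.0 ± 0.24 but stood at 0.05 after the correction. Procr, the protein C receptor, and Id3 were lower, by -1.20 ± 0.25 and -1.13 ± 0.23, and both missed the threshold when the values were rescaled. Id3 also missed it after the correction (-0.37, adjusted p = 0.130). Cd44 stood at 37.8 ± 9.78 against 27.6 ± 2.55 RPKM (adjusted p = 0.163) and Cd24a at 55.1 ± 13.1 against 59.5 ± 29.5 RPKM (adjusted p = 0.943), and neither passed. On rescaling to summed reads both were called higher (1.33 and 0.89, adjusted p = 0.000879 and 0.0263). The median change of all genes was then 0.86, near that of Cd24a. Cd24a was also called higher with the block and the correction together (0.70, adjusted p = 0.0443). Aldh1a1 and Prom1 lay below the filter at 0.408 ± 0.541 and 0.0105 ± 0.00945 RPKM in the stem-labelled clones. Of the luminal and milk genes, 6 of 10 rose and 2 fell (adjusted p = 0.241), among them Gata3, which specifies luminal cells, up from 3.39 ± 0.600 to 17.8 ± 3.47 RPKM, and Xdh, which encodes a protein of the milk fat globule, up from 7.60 ± 4.37 to 75.3 ± 32.3 RPKM.

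Pluripotency factors were near 0 except in replicate 1 of the other clones. That library held 458 reads over 15 such genes, where the other 5 libraries held 0 to 2 reads. Dppa5a had 86 reads there, Sox2 46, Nanog 31 and Pou5f1, which encodes OCT4, 21. None of the 15 passed the filter. Without that library 2706 genes were higher and 2223 lower, 4700 of them among the 5577 and in the same direction.

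Neither cell cycle list passed on the deposited values. Of 30 genes of the G2 and M phases, 3 rose, 8 fell and 19 did not pass (adjusted p = 0.496), or 1 and 1 when adjusted over the list alone. The kinase Nek2 rose by 1.03 ± 0.20, a call lost after the correction (0.45, adjusted p = 0.0550), and Cenpe, a motor of the kinetochore, changed by -0.88 ± 0.22 (-1.35 after the correction). Mki67, the proliferation marker, stood at 7.75 ± 3.38 against 11.4 ± 0.533 RPKM (-0.58 ± 0.28, adjusted p = 0.102), and changed by 0.27 when rescaled. It was called lower after the correction (-1.45, adjusted p = 0.000643, or 0.00204 with the block added), with limma-voom (-0.80, adjusted p = 0.0442) and without replicate 3 of the stem-labelled clones (-0.87, adjusted p = 0.0177). After the correction the G2 and M list passed with a median of -0.27 (adjusted p = 0.0468), a call lost when the block was added and, with adjusted p = 0.963, with an estimated correlation. Of 32 replication genes 7 rose, 7 fell and 18 did not pass (adjusted p = 0.895), or 5 and 4 when adjusted over the list alone. Among them E2f1, a transcription factor of S phase entry, changed by -1.65 ± 0.31, and Gins3, a subunit of the replicative helicase, rose from 2.46 ± 0.948 to 8.75 ± 1.01 RPKM (1.52 ± 0.23). Glycolysis genes did not pass as a list, with 4 of 20 higher and 6 lower (adjusted p = 0.427). Of 24 interferon response genes 1 rose and 6 fell (adjusted p = 0.332), and without replicate 3 of the other clones that list passed (median -0.67, adjusted p = 0.00822).

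Few marker genes of other cell types reached the filter. Of the leukocyte, fibroblast and endothelial markers 5 were tested, and of the erythroid and adipocyte markers 0. Pdgfra and Flt1 rose by 1.10 ± 0.23 and 1.01 ± 0.20 but stood at 0.15 and -0.08 after the correction. S100a8 and Egfl7 fell by 2.55 and 2.32 on the log2 scale, S100a8 missing the threshold after the correction (-1.31). Cd68, a glycoprotein of lysosomes, was at 29.0 ± 14.7 against 16.4 ± 11.9 RPKM (0.87 ± 0.55, adjusted p = 0.203). It was called higher with the replicate block (adjusted p = 0.0206), without replicate 2 of the other clones (1.40, adjusted p = 0.0401), after the correction (1.59, adjusted p = 0.0333) and on rescaling (1.74, adjusted p = 0.00790).

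In the test as a whole, 7 of 36 lists passed with the preset correlation, and the 29 others had adjusted p values from 0.129 to 0.973. With the correlation estimated camera called 0 lists, and 0 had an unadjusted p under 0.05. Each named gene described as higher or lower passed the test over all genes, and its 3 libraries of a group lay on the same side of all 3 of the other group. The groups could not be told apart from the way the libraries were prepared or counted, because the ratio of reads in genes to the authors' total parts them in the same way.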

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

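The correction for length and GC content, its combination with the block, the rescaling to summed reads and limma-voom were chosen after seeing the data. The 5577 calls became 3477 with a filter of mean RPKM at least 5 (1405 higher), which tests fewer genes, and 3438 at 2-fold or more (1487 higher). Rescaling gave 5926 higher and 1245 lower. In the other settings the totals stayed within 1.5 times. Leaving out a library gave 4286 to 5336 calls, 2068 to 3034 higher and 2149 to 2302 lower, and 6 to 7 lists. The filter was applied again to the libraries left, so only 9503 to 9787 genes were tested there. The data did not show a pairing by replicate number (correlations of deviations -0.12, 0.03 and -0.08 for equal numbers). With 3 libraries per group such correlations cannot exclude it. With the replicate numbers as a block 2735 genes were higher and 2477 lower. An estimated correlation left 0 of the 7 lists (camera). The comparison of deposited counts with deposited normalized values, intended beforehand, was not run, since the files hold normalized values alone. limma-voom on the recovered reads gave 2600 higher and 2872 lower.

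Of 75 called genes named, 66 kept their call in every setting that tested them and 9 lost it, all in settings added later: Id3, Itga6, Nek2, Npc1, S100a8, Pdgfra and Flt1 with the correction, and Id3, Procr and Cenpe on rescaling. Flt1 changed sign, to -0.078 with either form of the correction. The following did not pass the main test. With either form of the correction the median was -0.20 for the S phase list and 0.29 for immediate early genes, and the change was -0.11 for Cd44, 0.70 for Cd24a, 0.21 for Epcam, -0.049 for Vim, 0.57 for Snai1 and 0.033 for Krt8. On rescaling the medians were 0.42 for epithelial junction, 0.75 for G2 and M, 0.44 for glycolysis, 0.30 for amino acid response, 0.31 for interferon response and 0.38 for immediate early genes. The changes were 0.89 for Cd24a, 0.90 for Epcam, 0.20 for Snai1, 0.043 for Krt8 and 0.27 for Mki67. Rescaling moved the median of all genes from 0.11 to 0.86, and each of these list medians stayed below 0.86. The p53 list had medians of -0.063 with upper-quartile scaling, -0.022 with no filter, -1.46 with mean RPKM at least 5 and -0.083 with limma-voom. Leaving out a library moved G2 and M between -0.32 and 0.010, S phase between -0.00084 and 0.36, p53 between -0.10 and 0.16, interferon between -0.67 and 0.15, Cd24a between -0.27 and 0.34 and Epcam between -0.087 and 0.037. Apart from the shift of all genes on rescaling, the cause was not tested for any of these. Depth limits genes near 1 RPKM, such as the histone genes, which rest on few reads.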

Other observations

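Cdkn1a, the cell cycle inhibitor p21, fell from 118 ± 14.5 to 16 ± 2.16 RPKM in the stem-labelled clones (mean ± SD, n = 3 per group; log2 fold change -2.81 ± 0.22 SE), while Cdkn1b, the related inhibitor p27, rose from 3.94 ± 0.178 to 16.7 ± 3.37 RPKM (1.83 ± 0.21). Both belong to the list of p53 targets and growth arrest genes. Of its 16 tested genes 4 rose, 4 fell and 8 did not pass (camera adjusted p = 0.734). The list had a median of 0.04, a mean of -0.36 and a test direction of down. The NOTCH receptor genes Notch1 and Notch2 rose by 1.98 ± 0.19 and 1.97 ± 0.22 (1.55 and 1.16 after the length and GC correction). Of 8 NOTCH genes 4 were higher and 1 lower (camera adjusted p = 0.243), or 3 and 0 after the correction. Fgfr2 rose from 1.23 ± 0.0933 to 16 ± 7.66 RPKM (2.82 ± 0.31, 1.80 after the correction) and Axl from 72.7 ± 13.1 to 194 ± 31.8 RPKM. Of 22 growth factor receptor and ligand genes 10 were higher and 2 lower, with a median of 0.48 (camera adjusted p = 0.154). After the correction 4 were higher and 1 lower, with a median of 0.18 (camera adjusted p = 0.717). Ctgf and Cyr61, which respond to YAP, each changed by -2.50 on the scale of log2(RPKM + 1), which shrinks changes at low levels. Ctgf stood at 0.440 ± 0.186 against 7.12 ± 0.134 RPKM, a ratio of 16.2. Cyr61 stood at 14.8 ± 5.54 against 85.8 ± 17.8 RPKM, a ratio of 5.78. Of 20 genes of the YAP and TEAD list 10 rose and 3 fell (camera adjusted p = 0.130), or 7 and 3 after the correction.

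Matrix proteases moved apart: Mmp14, the membrane-bound collagenase, rose from 7.83 ± 3.13 to 43.3 ± 10.8 RPKM and Mmp9, a gelatinase, fell from 20.6 ± 0.513 to 1.91 ± 0.709 RPKM. Of 27 proteolysis and invasion genes 7 rose, 9 fell and 11 did not pass (adjusted p = 0.973), with a median of 0.42 and a mean of -0.03. Jun and the phosphatase Dusp4 rose by 2.18 ± 0.19 and 2.60 ± 0.26 and Dusp5 changed by -1.92 ± 0.21, among 25 immediate early genes of which 7 rose and 9 fell (adjusted p = 0.688). Shmt2 and Phgdh, enzymes of serine and glycine synthesis, fell by 2.34 and 1.88 on the log2 scale. Their list of amino acid response genes passed only after the length and GC correction (median -0.74, adjusted p = 0.0146 against 0.130), as did the endoplasmic reticulum stress list (0.49, adjusted p = 0.0468 against 0.174). Both calls were lost with an estimated correlation (adjusted p = 0.937 and 0.963), and that of the stress list also when the block was added. Pdia4 of the stress list rose by 1.36 ± 0.20. Stem-labelled libraries held more drug transporter transcripts for 7 of 11 genes and less for 1, with a median of 0.83 (camera adjusted p = 0.129). After the correction 3 were higher and 1 lower, with a median of 0.006 (camera adjusted p = 0.865).

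The tests of length and GC content, of the library ratio and of the reads of receptor genes beside pluripotency genes were chosen after the result was seen; the others were written before their values were known. Of the ribosomal protein and oxidative phosphorylation genes, 40 of 54 and 39 of 55 were called lower in the stem-labelled libraries and 0 higher. Both list calls were lost with an estimated correlation. The 109 genes had a median change of -1.63, below the range of 10000 random lists matched on length, GC content and level (median -1.09, central 95% from -1.38 to -0.83). The 2 lists are among those that passed in these data. The random lists hold unrelated genes, so their range is too narrow for correlated members (estimated correlation 0.626 and 0.470). Their median level was also lower, at 7.68 against 8.10 on the log2 scale. The comparison therefore leaves a bias by length and GC content open, as a part or as the whole cause. Reads shared with near-identical copies were argued against by the 27 members whose longest transcript shares no 50-base stretch. They had a median of -1.55 and 24 were below 0, although only 2 of them are ribosomal and shorter transcripts were not examined. A difference in library preparation or counting cannot be told apart from the groups, since the lowest ratio of reads in genes to the authors' total was 1.23 in the other libraries and the highest 0.757 in the stem-labelled ones. A difference between the kinds of clone stays open, untested.

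Of the lysosome and extracellular matrix genes, 17 of 36 and 15 of 23 were called higher in the stem-labelled libraries, and 2 and 3 lower. Both list calls were lost with an estimated correlation. Their 59 genes had a median change of 0.85, above the matched lists (median 0.15, central 95% from -0.17 to 0.41). These 2 lists, too, are among those that passed in these data. The matched lists again ignore the correlation between members (estimated at 0.340 and 0.101), so the comparison leaves length and GC bias open. Macrophages, which express Gpnmb, were argued against by Fcer1g, Lyz2, Laptm5, Ptprc and Csf1r, whose mean was at most 0.150% of the level of Gpnmb in a stem-labelled library, and fibroblasts by Dcn, Col1a1, Col1a2 and Pdgfra, whose mean was at most 0.519% of the level of Fn1. The files hold 5 of the 6 genes chosen for the first test and 4 of the 6 for the second. The same library ratio (1.23 against 0.757) keeps preparation or counting open beside a difference between the kinds of clone.

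Reads of pluripotency factors in replicate 1 of the other clones were a pattern seen in the data. A candidate source is RNA or reads of mouse embryonic stem cells, since of 16 further genes of these cells 14 had a larger share of the reads in genes in that library than in each of the other 5, among them Tdh with 65 reads and L1td1 with 52. That count does not separate RNA in the sample from reads assigned from another library, and no sort or gate is named in the labels. For a broad background in silent genes, 2 of 16 genes of other tissues were highest in that library, and of 24 olfactory and vomeronasal receptor genes, a set added later, 29.2% were, between the bounds set for it. By a comparison chosen after these counts, which argues against such a background at the level of the pattern, the receptor genes had a median of 0.50 reads there (upper quartile 3, 12 genes at 0) and the 15 pluripotency genes a median of 23 (lower quartile 12). The files hold 7 of the 16 tissue genes, and a biological source was not tested.

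The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes the real split gave 5577 and the highest other 0 (limma, 214 at an unadjusted p under 0.05), so 1 split gave as many. For lists the real split gave 7 and the highest other 13, and 9 of the 10 splits gave as many or more, so a count of 7 lists with the preset correlation was not larger than in other splits. Each other split mixes the groups, so part of the group difference stays in its contrast and part enters its spread. The other splits are therefore not free of the group difference, for genes or for lists. By chromosome, the largest median change after the correction was 0.34 on chromosome 18 (adjusted p = 0.0846), which lies between the bounds set for a gain or loss of a whole chromosome and for none.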
